A study of Danio rerio with 12 samples.

How the data were processed

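RNA from zebrafish brains was hybridized to 12 Affymetrix GeneChip Zebrafish Genome Arrays, 3 per group for isolated fish, mirror fighters, winners and losers. Per the labels' protocols, 100 ng of total RNA with poly-A controls spiked in was amplified and labelled with biotin by the 3 prime in vitro transcription kit of the manufacturer. The labels give conflicting RNA extractions: the series design names a lipid tissue column kit with a DNase step and the extraction protocol names Trizol. They do not say whether each array held the RNA of 1 fish or of a pool, whether winner and loser arrays with the same number came from the same fight, or on which days arrays were processed.

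The values analysed are the deposited series table, 1 linear signal intensity per probe set and array, per the labels made with an unstated summary and normalization method. The submitters' processing notes name Partek 6.6 as the only tool, without its role. The values had a floor of exactly 1, with 12 to 24 probe sets per array at it, and were not quantile normalized. Identical values made up at most 0.109% of any pair of arrays, so no array was a copy of another. All value columns were matched to an array of the labels and used. Raw image files were not used here.

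The log2 of each value was taken without an offset. The 115 control probe sets were left out of the tests, which left 15502. The platform annotation given with the data paired 10795 of them with 1 gene symbol, 135 with several and 4572 with none. Of the single-symbol probe sets, 10711 had a gene identifier found in the zebrafish gene table, an assembly named GRCz12tu, which was used for current names only. No genome build is named in the labels, so no coordinates are given. Genes were named only from probe sets with 1 symbol. Probe sets whose mean log2 over all arrays lay under 5.02, the dimmest 25%, are called dim.

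A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom per probe set and 2.55 prior degrees of freedom from empirical Bayes moderation. The 7 contrasts were winners, losers and mirror fighters each against isolated fish, winners against losers, winners and losers each against mirror fighters, and the mean of winners and losers against mirror fighters, with an F-test for any difference among the 4 groups. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. All p-values are two-sided, and n is 3 arrays per group. Differences of single measures, such as the spiked controls, were tested by exact permutation.

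The groups, contrasts, alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined. Named were, per contrast, the 12 largest rises and 12 largest falls among called single-symbol probe sets whose groups did not overlap, with 1 probe set per gene, that with the smallest p. Where fewer passed, places up to 5 per direction were filled by smallest p and are given as values. From each list up to 3 members with the smallest p and every called member were named. Genes outside this rule are marked where they appear. Of 82 named rises and falls over the 7 contrasts, 22 were of genes with other probe sets, and for 19 of these all pointed the same way. The exceptions included btg2 in winners and fli1 in losers, each against isolated fish. Values filled in by smallest p were not counted, and among them spint1b and sft2d1 also had a probe set pointing the other way.

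Lists with at least 5 measured genes were tested with 1 probe set per gene, the brightest, by camera with its preset inter-gene correlation of 0.01, adjusted over the 26 lists of a contrast. They were also tested with the correlation estimated from the data and by fry. The value of fosab in list results and in the comparison of mirror fighters with isolated fish is therefore from a different probe set than in the other gene results. The immediate early list shares 1 of its 49 genes, cebpd, with the stress axis list, which shares 5 of its 16 with other lists.

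The scripts were tested on simulated data with the real arrays' means and spread and 200 changed probe sets of 15502. For winners against isolated fish 46% of changes of log2 1 and 80% of log2 2 were recovered, and 6.67% of 135 calls were false. For winners and losers against mirror fighters 61% and 89% were recovered, and 6.25% of 160 calls were false. A shift of 0.5 in the immediate early genes was found in 20 of 20 simulations of winners against isolated fish, and 0 of 480 tests of unchanged lists were called. The noise was drawn independently for each probe set. These simulations therefore do not show how often lists of genes that vary together between arrays are falsely called.

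Whether replicate numbers pair arrays was checked from the correlation of same-numbered arrays' deviations from their group means. For winners and losers these were 0.112, 0.111 and 0.233, each over 0.1, so these arrays were taken as paired from the data, and the fit with replicate number as a block is given beside comparisons that hold both groups where it changed a list call or moved a count by over 1.5 times. No other pair of groups had all 3 correlations over 0.1. Comparisons that share control arrays were set beside 20 simulations of unchanged groups. Alternatives tried were quantile normalization, centring on the median, leaving out dim probe sets, no moderation, moderation with a trend and robust to outliers, the replicate block, the mean of a gene's probe sets, only the arrays compared and leaving out each array in turn. After seeing the data, 32 added before log2, the hybridization control level as a covariate, a winner and loser fit with replicate block, the named genes with only the arrays compared, and list tests with the block and an estimated correlation were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.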

Results

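Gene expression was measured in the brains of adult AB wild-type zebrafish on 12 one-colour Affymetrix zebrafish arrays, 3 for each of 4 social experiences. Isolated fish met no opponent. Mirror fighters fought their own image, a fight that nobody wins or loses. Winners and losers came from fights between real opponents. All fish had been isolated for 5 days before, and brains were taken after 30 min of the manipulation. Each array gave a signal for 15502 probe sets after the removal of 115 control probe sets, and 10795 of them carried a single gene symbol, for 8793 genes. The median intensity per array lay between 94.1 and 104, and between 23.2% and 26.5% of the probe sets on an array read below 32. Arrays of the same group correlated at 0.957 to 0.977 on the log2 scale. Arrays were not always nearest to their own group. Isolated array 1 and mirror fighter array 1 correlated at 0.979, and winner array 2 was nearest to isolated array 3 (0.97). The number of arrays limits the precision, and since the labels do not say whether an array held 1 brain or a pool, the p-values measure only the spread between samples.

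The controls spiked into every sample did not read alike in all groups. The bacterial hybridization controls, 14 probe sets, averaged a log2 intensity of 9.37 ± 0.12 (SD, n = 3) in isolated fish and 9.40 ± 0.10 in mirror fighters, against 10.48 ± 0.25 in winners and 10.35 ± 0.32 in losers. The 6 winner and loser arrays were thus 2.05-fold brighter than the other 6, with no overlap, and the poly-A controls added before labelling were 1.43-fold brighter. A two-sided exact permutation test over the 924 splits of the 12 arrays, taken as independent, gave p = 0.00216 for each of these controls, the smallest value it can give. The ratio of 3 prime to 5 prime signal of GAPDH, a measure of RNA integrity, differed by -0.04 between the same sets of arrays (exact permutation p = 0.346). The median of all tested probe sets was lower by a log2 difference of -0.06 on the winner and loser arrays (exact permutation p = 0.00866). Each comparison of winners or losers with isolated fish or mirror fighters therefore contained a difference in spiked controls, while winners and losers differed in the hybridization, poly-A and cre controls by 0.13, 0.01 and 0.07. Mirror fighters differed from isolated fish in the same controls by 0.02, -0.17 and -0.08, with the cre control lower on each of the 3 mirror fighter arrays than on any isolated array.

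**Figure D1:**
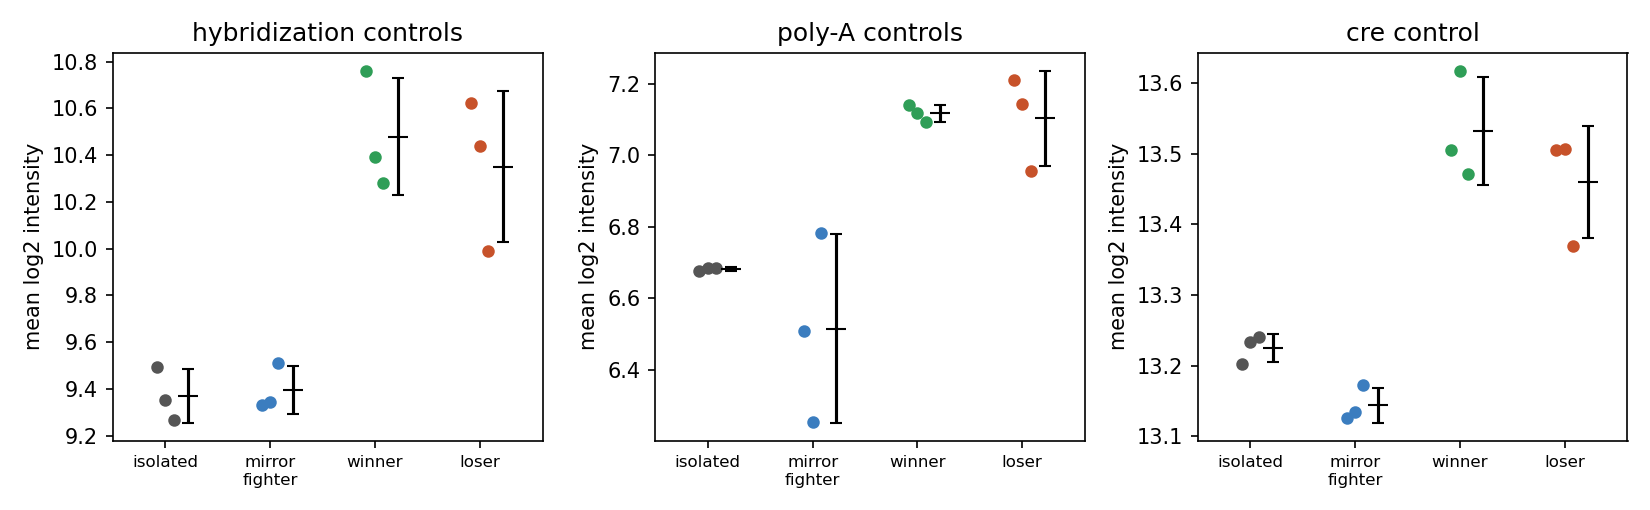
Mean log2 intensity of the spiked controls on each array (points) with the group mean and SD (bars, n = 3). The 6 winner and loser arrays lie above all 6 isolated and mirror fighter arrays for the hybridization, poly-A and cre controls.

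Winners were compared with isolated fish, a fight won against a real opponent set against no social contact, on arrays that also differed in spiked controls. The largest rises were in genes that neurons switch on within minutes of being activated. The neuronal activity factor npas4a rose 13.8-fold, from a log2 intensity of 7.71 ± 0.45 to 11.50 ± 0.34 (SD, n = 3). The nuclear receptor nr4a1 rose by a log2 difference of 2.92 ± 0.29 (SE), the AP-1 subunit fosab by 2.34 ± 0.23, the cytokine signalling inhibitor socs3a by 2.31 ± 0.35 and the zinc finger factor egr4 by 2.00 ± 0.26. Further rises were those of the kinase gene sik1 (3.24-fold), the antiproliferative gene btg2 (2.82-fold), the AP-1 subunit junba (2.52-fold), the stress-inducible gadd45ba (2.50-fold), egr2b (2.41-fold) and egr2a (2.40-fold). Outside this family, the major vault protein gene mvp rose by 2.01 ± 0.29, the uncharacterised wu:fj62d01 by 1.71 ± 0.17 and the neurotrophin gene bdnf by 0.96 ± 0.14, and the ferrochelatase gene fech, a dim probe set, by 1.37 ± 0.23. The purine salvage gene pnp6 fell by 1.33 ± 0.21, wu:fi37e09 by 1.09, zgc:92664 by 1.00, the phosphatase gene cpped1 by 0.93 and the selenoprotein gene selenoh by 0.81, and the dim tnfaip8l2a was at 0.407-fold of its isolated level.

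Among 49 measured immediate early genes, 11 rose in winners, none fell and 38 did not pass over all probe sets, while adjusted over the list alone 22 rose and 2 fell. The 2 that fell, the dim klf11b (-1.04 ± 0.30) and maff (-0.58 ± 0.17), were named after their values were seen. The median log2 difference of the list was 0.56 (camera adjusted p = 1.29e-12, and adjusted p = 0.000419 with an estimated correlation), with 39 members above 0. Synaptic plasticity genes had a median of 0.27 (23 members, adjusted p = 0.00228, and adjusted p = 0.26 with an estimated correlation). Of these, bdnf rose, none fell and 22 did not pass, and 4 rose adjusted over the list alone, the others being the scaffold gene dlg1a (0.77 ± 0.17), neurod1 (0.49 ± 0.13) and the adhesion gene nlgn1 (1.21 ± 0.34), the last named after its value was seen. Markers of microglia and leukocytes had a median of -0.80 (27 members, 24 below 0, adjusted p = 0.000203, and adjusted p = 0.496 with an estimated correlation). No microglial marker passed over all probe sets and 6 fell adjusted over the list alone, among them cxcr4b (-1.25 ± 0.29), coro1a (-1.91 ± 0.48) and ncf1 (-1.65 ± 0.41).

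Meningeal and connective tissue genes in winners had a median of -0.45 (19 members, adjusted p = 0.00299, and adjusted p = 0.245 with an estimated correlation), and tgfbi (-0.83 ± 0.20) and the collagen gene col1a1a (-0.79 ± 0.22) fell adjusted over the list alone. This median ranged from -0.48 to -0.24 over the fits without 1 array, the latter without winner array 1, and the call stayed. The other calls came from members none of which passed even adjusted over the list alone. Glucocorticoid and stress axis genes had a median of 0.37 (16 members, adjusted p = 0.027, and adjusted p = 0.377 with an estimated correlation), a call that ended without isolated array 3 (adjusted p = 0.0607) or winner array 3 (adjusted p = 0.121). Neuronal genes had a median of 0.19 (17 members, adjusted p = 0.00616, and adjusted p = 0.496 with an estimated correlation), which did not pass without winner array 2 (adjusted p = 0.0645). Liver and plasma protein genes had a median of 0.36 (22 members, adjusted p = 0.0355, and adjusted p = 0.245 with an estimated correlation), not passing without isolated array 2 (adjusted p = 0.0511), isolated array 3 (adjusted p = 0.108) or winner array 1 (adjusted p = 0.119). Interferon and immune genes had a median of -0.66 (27 members, adjusted p = 0.049, and adjusted p = 0.722 with an estimated correlation), not passing without isolated array 2 (adjusted p = 0.384), loser array 1 (adjusted p = 0.0749), mirror fighter array 2 (adjusted p = 0.0534), winner array 1 (adjusted p = 0.0536) or winner array 3 (adjusted p = 0.287).

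In all, limma called 38 probe sets between winners and isolated fish, 29 higher and 9 lower in winners, for 29 named genes. The winner and isolated arrays did not overlap at 23.8% of all probe sets, where chance gives 10%. Quantile normalization gave 26 higher and 4 lower, and centring each array on its median gave 31 higher and 2 lower. Other settings evened the balance, with 32 higher and 27 lower without the dimmest 25% and 33 higher and 32 lower with 32 added before log2. The count fell to 16 without isolated array 1, 15 without isolated array 2, 19 without loser array 1, 25 without loser array 2, 16 without mirror fighter array 1, 24 without mirror fighter array 3, 18 without winner array 1 and 17 without winner array 2. The calls of npas4a, nr4a1, fosab, sik1, egr2b and wu:fj62d01 did not depend on any 1 array. All 6 named falls lost their calls in most of the 21 or 22 alternative settings each was run under (16 to 18), as did fech (18) and egr2a (15). In this comparison limma called 0 probe sets with the hybridization control level as a covariate, with 1579 at an unadjusted p under 0.05. That level separated these groups without overlap, so the covariate can hardly be parted from the group difference. Lost calls under it decide nothing about a cause, here and in the comparisons below.

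**Figure D2:**
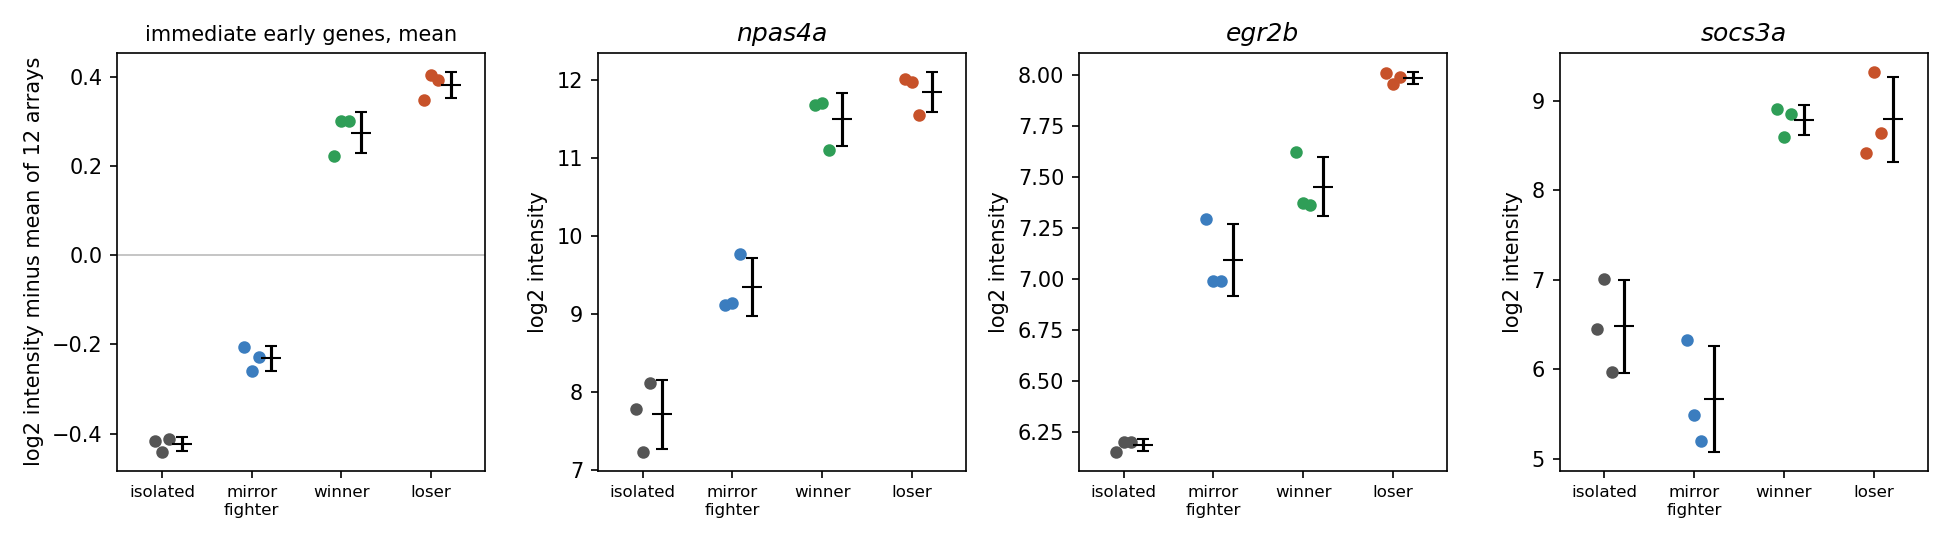
Mean log2 intensity of the 49 immediate early genes, as the difference from the mean of all 12 arrays, and log2 intensity of npas4a, egr2b and socs3a on each array (points), with the group mean and SD (bars, n = 3). The list mean is -0.42 in isolated fish, -0.23 in mirror fighters, 0.27 in winners and 0.38 in losers.

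Losers were compared with isolated fish, a fight lost to a real opponent set against no social contact, again on arrays that differed in spiked controls. The same family led: npas4a rose 17.6-fold (log2 4.14 ± 0.27, SE, n = 3), nr4a1 9.04-fold, fosab by a log2 difference of 2.98 ± 0.23, egr4 by 2.64 ± 0.26, socs3a by 2.31 ± 0.35, sik1 by 1.98, btg2 by 1.82, egr2b by 1.80 ± 0.13 and junba by 1.72. In addition egr2a rose by 1.55, egr1 by 1.54 ± 0.28, gadd45ba by 1.25 and the phosphatase genes dusp5 and dusp2, which restrain MAP kinases, by 1.16 and 1.13. Also higher were wu:fj62d01 (2.27 ± 0.17), mvp (2.03 ± 0.29), the dim fech (1.80 ± 0.23) and bdnf (1.01 ± 0.14). Among the falls, the largest were in dim probe sets, those of serpina1l (-2.82 ± 0.42) and ptpdc1b (-2.42 ± 0.36). Better lit probe sets that fell were those of tax1bp3 (-1.85 ± 0.31), the chromatin gene rsf1b.1 (-1.79 ± 0.33), pcxa, which encodes pyruvate carboxylase (-1.66 ± 0.28), and si:dkey-100n23.3 (-1.64 ± 0.21). Lower too were nudt2 (-1.41 ± 0.25), the cyclin gene ccnb3 (-1.37 ± 0.19), the vascular transcription factor gene fli1 (-1.33 ± 0.25) and otpb (-1.17 ± 0.16), a homeobox gene of neuroendocrine hypothalamic neurons. The other probe set of fli1 pointed the other way. The dim rtkn2 and carhsp1 fell by 1.64 and 1.24.

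Of the 49 immediate early genes 14 rose in losers, none fell and 35 did not pass, and adjusted over the list alone 24 rose and 2 fell. Those 2 were again the dim klf11b (-1.08 ± 0.30) and maff (-0.76 ± 0.17), named after their values were seen. The list median was 0.48 (adjusted p = 3.95e-15, and adjusted p = 0.000212 with an estimated correlation), with 40 members above 0. Glucocorticoid and stress axis genes had a median of 0.42 (adjusted p = 0.0324, and adjusted p = 0.41 with an estimated correlation). None of its members passed over all probe sets and 5 rose adjusted over the list alone: the glucocorticoid targets klf9 (2.56 ± 0.73) and tsc22d3 (0.65 ± 0.17), cebpd (1.98 ± 0.56), which the immediate early list also holds, and, named after their values were seen, fkbp5 (2.48 ± 0.78) and the dim gluconeogenesis gene pck1 (1.61 ± 0.52). This call ended without isolated array 2 (adjusted p = 0.0529), isolated array 3 (adjusted p = 0.0534) or loser array 3 (adjusted p = 0.0566). Synaptic plasticity genes had a median of 0.17 (adjusted p = 0.0352, and adjusted p = 0.507 with an estimated correlation), where bdnf rose over all probe sets and dlg1a (0.90 ± 0.17) also adjusted over the list alone. That call ended without isolated array 1 (adjusted p = 0.103), isolated array 2 (adjusted p = 0.0682), loser array 2 (adjusted p = 0.0515) or loser array 3 (adjusted p = 0.0715). Meningeal genes had a median of -0.32 (adjusted p = 0.0352, and adjusted p = 0.402 with an estimated correlation), with falls adjusted over the list alone in timp2b (-1.13 ± 0.23) and tgfbi (-0.95 ± 0.20), and did not pass without isolated array 2 (adjusted p = 0.0536) or loser array 3 (adjusted p = 0.148).

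Between losers and isolated fish limma called 88 probe sets, 40 higher and 48 lower in losers, for 64 named genes, and 26.2% of probe sets did not overlap, where chance gives 10%. The balance of directions depended on the setting. Rises led with 44 higher and 27 lower after quantile normalization and 47 higher and 13 lower after centring on the median. Falls led with 79 higher and 192 lower without the dimmest 25%, 91 higher and 226 lower with 32 added, 63 higher and 99 lower with trend and robust moderation, 39 higher and 58 lower without moderation, and 41 higher and 77 lower after averaging a gene's probe sets. The count was 22 without isolated array 1, 21 without isolated array 2, 35 without loser array 1, 51 without loser array 2, 39 without mirror fighter array 1, 47 without mirror fighter array 3 and 57 without winner array 2. The calls of rsf1b.1, rtkn2, nudt2, fli1 and carhsp1, 5 of the 12 named falls, and of egr1 and dusp2 were lost in most of the alternative settings. With the hybridization control level as a covariate the count was 0, with 1379 at an unadjusted p under 0.05.

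**Figure D3:**
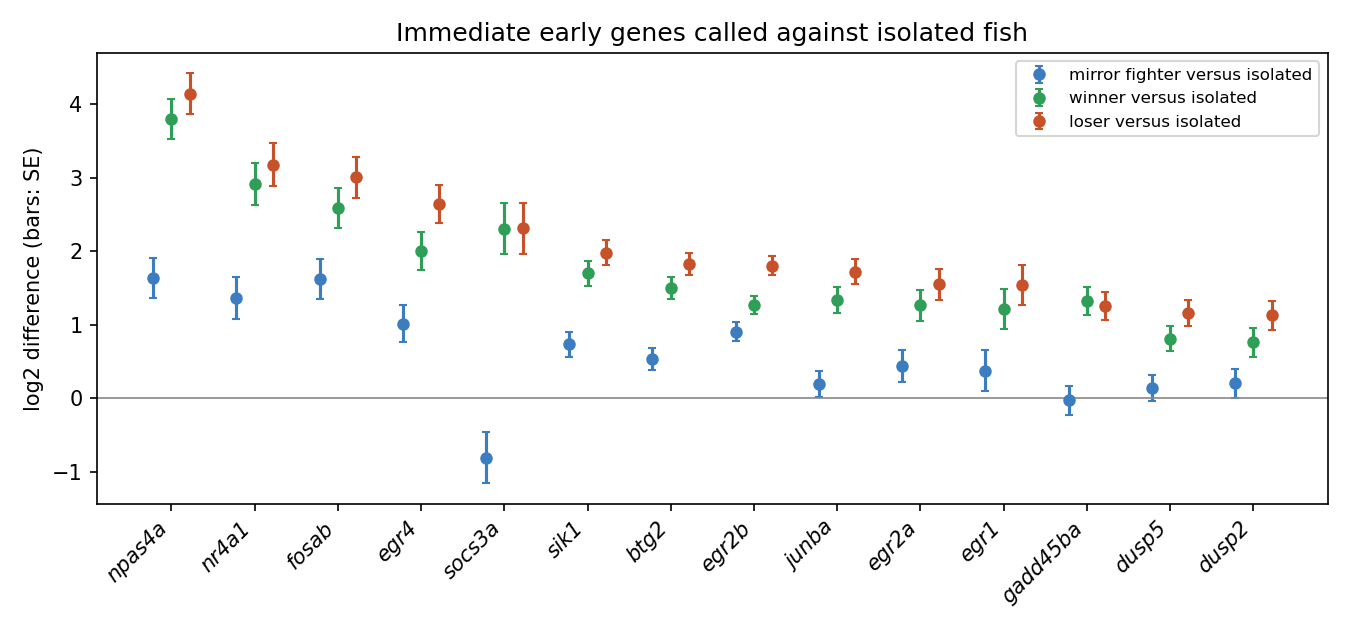
Log2 difference from isolated fish (points, with SE as bars, 3 arrays per group) of the immediate early genes called in winners or losers, 1 probe set per gene. The points of npas4a lie at 1.64 in mirror fighters, 3.79 in winners and 4.14 in losers, and those of socs3a at -0.81, 2.31 and 2.31.

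Winners and losers shared 31 of these calls, 27 higher and 4 lower than in isolated fish, and none in opposite directions. Independent lists of these sizes would share 0.0748 higher and 0.0279 lower probe sets. Simulated unchanged groups set against the same isolated arrays shared 0, but they hold no real differences and so could share hardly any calls, which gives no baseline for the shared count. Across all probe sets the log2 differences of winners and of losers correlated at 0.749, against 0.5 in the simulation, with a covariance of 0.175 against 0.0594, a difference of 0.115. Genes are not independent replicates, and part of the excess may come from the 3 isolated arrays, which are too few to be divided between the comparisons. The simulation also held neither the brighter spiked controls that winner and loser arrays share nor their pairing by number.

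Mirror fighters were compared with isolated fish, a fight without an outcome or a real opponent set against no social contact. Here no single gene passed over all probe sets, but the immediate early genes as a group were higher. The 49 members had a median log2 difference of 0.10 and a mean of 0.19, with 33 above 0 (adjusted p = 0.00027, and adjusted p = 0.0253 with an estimated correlation). The median ranged from 0.06 without isolated array 2 to 0.15 without mirror fighter array 2, and the call stayed without any 1 array. No member passed over all probe sets, while adjusted over the list alone 7 rose and none fell. These were npas4a (1.64 ± 0.27, SE, n = 3), fosab (1.62 ± 0.27) and egr2b (0.91 ± 0.13), together with nr4a1 (1.36 ± 0.29), egr4 (1.02 ± 0.26), sik1 (0.73 ± 0.17) and btg2 (0.53 ± 0.15), of which egr4, sik1 and btg2 were named after their values were seen. The adjusted p over all probe sets was 0.135 for egr2b and 0.192 for npas4a and fosab. In the same comparison socs3a stood at -0.81 ± 0.35, gadd45ba at -0.03 ± 0.19 and bdnf at 0.05 ± 0.14. Among genes outside the lists, the smallest p-values belonged to values that did not pass, such as tspan9b (0.499-fold), rsf1b.1 (-2.16 ± 0.33), spint1b (-1.94 ± 0.31), dnm1a (-2.06 ± 0.34), slc20a2 (-1.27 ± 0.22) and the dim bmp6 (2.21 ± 0.46).

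Glucocorticoid and stress axis genes in mirror fighters had a median of 0.39 (13 of 16 above 0, adjusted p = 0.000596, and adjusted p = 0.306 with an estimated correlation), with none passing adjusted over the list alone. Their lowest p-values belonged to klf9 (2.47), pfkfb4b (1.02) and tsc22d3 (0.60). Microglial markers had a median of -0.53 (24 of 27 below 0, adjusted p = 0.000141, and adjusted p = 0.901 with an estimated correlation), with no member passing. Over the fits without 1 array that median ranged from -0.65 to -0.28, the latter without isolated array 2, and the call stayed. Oxidative phosphorylation genes had a median of 0.09 (56 of 63 above 0, adjusted p = 0.00027, and adjusted p = 0.999 with an estimated correlation). Without isolated array 3 their median was -0.03 and the call ended (adjusted p = 0.664), as it did without mirror fighter array 2 (adjusted p = 0.207). Circadian clock genes had a median of -0.07 (30 members, adjusted p = 0.0488, and adjusted p = 0.999 with an estimated correlation). That call ended without isolated array 3 (adjusted p = 0.664), mirror fighter array 1 (adjusted p = 0.199), mirror fighter array 2 (adjusted p = 0.682), loser array 1 (adjusted p = 0.072), winner array 1 (adjusted p = 0.0729), winner array 2 (adjusted p = 0.0519) or winner array 3 (adjusted p = 0.0674).

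Between mirror fighters and isolated fish limma called 0 probe sets over all tested, with 594 at an unadjusted p under 0.05, where chance gives 775, and the smallest adjusted p was 0.135. That number depended on the fit. It was 874 with only the arrays compared and 715 with the replicate block, each with 0 calls. The arrays did not overlap at 10.7% of probe sets, where chance gives 10%. A single probe set passed (1) without isolated array 1, isolated array 3, loser array 2 or mirror fighter array 2. The log2 differences of mirror fighters correlated with those of winners at 0.455, against 0.498 in simulated unchanged groups sharing the isolated arrays, with a covariance of 0.0724 against 0.0597. With losers the correlation was 0.453, against 0.501, and the covariance 0.073 against 0.0598.

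Winners compared with losers separate the outcomes of a real fight. The immediate early genes stood lower in winners, with a median log2 difference of -0.11 and 34 of 49 members below 0 (adjusted p = 0.00189, and adjusted p = 0.0445 with an estimated correlation). No member passed, over all probe sets or adjusted over the list alone. The lowest p-values in this list belonged to egr2b (-0.53 ± 0.13, SE, n = 3), egr4 (-0.64 ± 0.26) and, in the other direction, the repressor gene crema (0.46 ± 0.20). Without loser array 3 the list did not pass (adjusted p = 0.0813). Microglial markers also stood lower in winners, with a median of -0.54 (23 of 27 below 0, adjusted p = 4.2e-06, and adjusted p = 0.94 with an estimated correlation), not passing without loser array 2 (adjusted p = 0.0669). Their median ranged from -0.97 without loser array 3 to -0.22 without loser array 2. On loser arrays 1 to 3 the list mean was 0.16, 0.61 and -0.61, and on winner arrays 1 to 3 it was -0.81, -0.08 and -0.56. Same-numbered winner and loser arrays varied together, and with the replicate number as a block interferon and immune genes were also lower in winners (median -0.17, adjusted p = 0.0133, against 0.155 without the block, and adjusted p = 0.992 with the block and an estimated correlation). The immediate early list passed with the block (adjusted p = 0.00383) and did not with the block and an estimated correlation (adjusted p = 0.119).

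No gene passed between winners and losers: limma called 0 probe sets, with 642 at an unadjusted p under 0.05 against 775 by chance and a smallest adjusted p of 0.387, and 0 with the replicate block. The values nearest to passing were those of 4 dim probe sets, cela1.5 (-1.06 ± 0.15, with values at the floor), the claudin gene cldnd (-2.67 ± 0.43), zgc:66156 (-1.51 ± 0.24) and sft2d1 (-1.42 ± 0.25), and of the splicing gene prpf3 (-0.82 ± 0.15). All isolated, mirror fighter and winner arrays read cela1.5 at the floor, so its SE rests largely on arrays without any spread. In the other direction stood the dim serpina1l (2.13 ± 0.42), ptpdc1b (1.77 ± 0.36) and zgc:172136 (0.59 ± 0.13), and the better lit ndrg4 (4.55 ± 0.96) and si:dkey-100n23.3 (0.94 ± 0.21). The SE of ndrg4 was widened by the mirror fighter arrays, with an SD of 2.59, against 0.38 in winners and 0.21 in losers. The arrays did not overlap at 6.58% of probe sets, where chance gives 10%. One array left out gave at most 2 calls, without winner array 3, and 1 without loser array 1, loser array 2, mirror fighter array 2 or winner array 1.

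Winners and losers were each compared with mirror fighters, a real fight with an outcome set against a mirror fight without one. These groups differ in the real opponent and the spiked controls as well as in the outcome, and the design cannot tell these apart. The clearest gene was socs3a, which rose 8.65-fold in winners (log2 3.11 ± 0.35, SE, n = 3, adjusted p = 0.043) and 8.69-fold in losers (3.12 ± 0.35, adjusted p = 0.00965). In losers npas4a also rose, by 2.50 ± 0.27, fosab by 2.01 ± 0.23, nr4a1 by 1.81, egr4 by 1.63, junba by 1.53, btg2 by 1.29, gadd45ba by 1.28, sik1 by 1.25 and egr2b by 0.90. The brighter probe set of fosab stood at 1.38 ± 0.27 and did not pass (adjusted p = 0.087). Beyond that family losers had more of tcima (1.65 ± 0.20), wu:fj62d01 (1.48 ± 0.17), the kinase gene pim1 (1.21 ± 0.13), dlg1a (1.15 ± 0.17) and bdnf (0.97 ± 0.14). Falls in losers were those of si:dkey-100n23.3 (-1.50 ± 0.21), otpb (-1.25 ± 0.16) and drg2 (-0.96 ± 0.15). For winners the next values did not pass: pim1 stood at 1.00 ± 0.13 and npas4a at 2.16 ± 0.27 (both adjusted p = 0.0514), gadd45ba at 1.35 ± 0.19, bdnf at 0.91 ± 0.14, ahcy at -1.23 ± 0.18 and pnp6 at -1.31 ± 0.21.

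The immediate early genes had a median of 0.36 in winners against mirror fighters (39 of 49 above 0, adjusted p = 1.08e-09, and adjusted p = 0.00111 with an estimated correlation), where socs3a rose, none fell and 48 did not pass, with 21 rising adjusted over the list alone. In losers against mirror fighters the median was 0.41 (38 above 0, adjusted p = 1.27e-13, and adjusted p = 0.000315 with an estimated correlation), 9 rose, none fell and 40 did not pass. Adjusted over the list alone 20 rose and 2 fell, nr4a2b (-0.51 ± 0.19) and maff (-0.51 ± 0.17), both named after their values were seen. Synaptic plasticity genes had medians of 0.25 in winners (adjusted p = 0.00107, and adjusted p = 0.326 with an estimated correlation) and 0.15 in losers (adjusted p = 0.0301, and adjusted p = 0.678 with an estimated correlation), the latter not passing without loser array 3 (adjusted p = 0.0638). Adjusted over the list alone 5 rose in winners and 3 in losers, dlg1a, bdnf and neurod1 in both, with nlgn1 and the glutamate receptor gene gria2a (0.70 ± 0.23) in winners, both named after their values were seen. Meningeal genes had medians of -0.47 in winners (adjusted p = 0.00465, and adjusted p = 0.285 with an estimated correlation) and -0.30 in losers (adjusted p = 0.0301, and adjusted p = 0.636 with an estimated correlation), the latter not passing without loser array 3 (adjusted p = 0.155) or mirror fighter array 1 (adjusted p = 0.0611). Adjusted over the list alone 2 fell in winners, tgfbi and foxc1b, and 4 in losers, timp2b, tgfbi, foxc1b and, named after its value was seen, foxc1a. Neuronal genes in winners had a median of 0.13 (adjusted p = 0.00835, and adjusted p = 0.81 with an estimated correlation), not passing without winner array 2 (adjusted p = 0.0898). Clock genes in losers had a median of 0.17 (adjusted p = 0.0301, and adjusted p = 0.888 with an estimated correlation), with the dim cry3a (0.60 ± 0.13) and nfil3-6 (0.77 ± 0.20) rising adjusted over the list alone. That call ended without loser array 1 (adjusted p = 0.0561), loser array 3 (adjusted p = 0.155), mirror fighter array 1 (adjusted p = 0.0968) or mirror fighter array 2 (adjusted p = 0.109).

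Against mirror fighters limma called 1 probe set in winners, socs3a, with 2611 at an unadjusted p under 0.05, and 27 in losers, 22 higher and 5 lower. Arrays did not overlap at 22.7% and 24.2% of probe sets, where chance gives 10%. For losers, centring on the median gave 25 higher and 2 lower, against 34 higher and 37 lower without the dimmest 25%, 17 higher and 21 lower without moderation and 29 higher and 24 lower with 32 added. With the hybridization control level as a covariate the counts were 0 in winners and in losers, with 1603 and 1392 at an unadjusted p under 0.05. Without mirror fighter array 2 the 27 calls in losers became 0, and 1 without mirror fighter array 1 or loser array 2, 9 without winner array 2, 10 without isolated array 1 or isolated array 2, 11 without loser array 1 or mirror fighter array 3, and 14 without isolated array 3. In winners socs3a did not pass in 9 of the 12 fits without 1 array. Without isolated array 1, isolated array 3, loser array 1, loser array 3, winner array 1 or winner array 2 there were 0 calls. Without mirror fighter array 2 or mirror fighter array 3 another probe set was the 1 call, and without winner array 3 there were 5 others. In losers the calls of nr4a1, egr4, gadd45ba, egr2b, dlg1a and drg2 were lost in most of the alternative settings, as was that of socs3a in winners (13 of 22). The covariance of these comparisons was 0.139, against 0.0605 in simulated unchanged groups set against the same mirror fighter arrays, at correlations of 0.704 and 0.505, and socs3a was the 1 call they shared. Here too the simulation lacked the brighter spiked controls that winner and loser arrays share and their pairing by number.

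The mean of winners and losers compared with mirror fighters sets 6 arrays against 3, where the series asks whether the fight needs an outcome. Mirror fighters lacked a real opponent as well as an outcome, and the spiked controls differed too. This comparison cannot tell these differences apart. The rise of socs3a was 8.67-fold (log2 3.12 ± 0.30, SE) and that of npas4a 5.03-fold (2.33 ± 0.24), both at an adjusted p of 0.00644. Other members of the immediate early family that rose were fosab (1.69 ± 0.20), nr4a1 (1.68 ± 0.25), junba (1.33), gadd45ba (1.32), egr4 (1.31), btg2 (1.13), dusp5 (0.85), egr2b (0.63) and sik1 (2.15-fold). The brighter probe set of fosab stood at 1.17 ± 0.24 and did not pass (adjusted p = 0.0589). The synaptic genes dlg1a and bdnf rose by 1.09 ± 0.15 and 0.94 ± 0.12, and tcima by 1.40 ± 0.17. Further rises were those of wu:fj62d01 (2.30-fold) and of the dim ank1a (1.66) and fech (1.14). Among the falls, the transcription factor genes sox3, her6 and her9 fell by 1.04 ± 0.18, 0.84 ± 0.15 and 0.71 ± 0.13. Also lower were the dim ptbp1a (-1.34 ± 0.23), a splicing regulator gene, and tmem30b (-1.03), the vitamin E transfer protein gene ttpa (-1.22), ahcy of the methionine cycle (-1.12 ± 0.16), si:dkey-100n23.3 (-1.03), tagln3b (-1.02), otpb (-1.01 ± 0.14), cyp3c1 (-0.89), rer1 (-0.88) and the G protein subunit gene gng3 (-0.84).

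In this comparison the immediate early genes had a median of 0.40 (37 of 49 above 0, adjusted p = 3.98e-12, and adjusted p = 0.000486 with an estimated correlation), 10 rose, none fell and 39 did not pass. Adjusted over the list alone 20 rose and 1 fell, maff (-0.42 ± 0.15), named after its value was seen. Synaptic plasticity genes had a median of 0.18 (adjusted p = 0.00515, and adjusted p = 0.481 with an estimated correlation), with bdnf and dlg1a rising, none falling and 21 not passing. Adjusted over the list alone 4 rose, the others being neurod1 (0.52 ± 0.12) and gria2a (0.69 ± 0.20), the last named after its value was seen. Meningeal genes had a median of -0.38 (adjusted p = 0.0087, and adjusted p = 0.355 with an estimated correlation), with none passing over all probe sets. Adjusted over the list alone 4 fell, timp2b (-0.78 ± 0.20), tgfbi (-0.75 ± 0.17), foxc1b (-0.72 ± 0.17) and, named after its value was seen, foxc1a (-0.81 ± 0.22). Clock genes had a median of 0.18 (adjusted p = 0.0278, and adjusted p = 0.869 with an estimated correlation), with 4 rising adjusted over the list alone, the dim cry3a (0.58 ± 0.12), nfil3-6 (0.69 ± 0.17), bmal1b (0.90 ± 0.25) and, named after its value was seen, clockb (0.44 ± 0.12). The clock call ended without loser array 3 (adjusted p = 0.0762), mirror fighter array 1 (adjusted p = 0.0876), mirror fighter array 2 (adjusted p = 0.135) or winner array 1 (adjusted p = 0.0789).

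Against mirror fighters limma called 65 probe sets in winners and losers together, 39 higher and 26 lower, for 45 named genes, and 12.8% of probe sets did not overlap, where chance gives 2.38%. The winner and loser arrays joined here varied together by number. With the replicate number as a block limma called 27 probe sets, 23 higher and 4 lower, 24 of them among the 65. The split was 29 higher and 8 lower after quantile normalization and 37 higher and 5 lower after centring on the median. Falls led in other settings, with 114 higher and 202 lower without the dimmest 25%, 129 higher and 223 lower with 32 added, 48 higher and 97 lower without moderation, 102 higher and 113 lower with trend and robust moderation, and 42 higher and 78 lower after averaging a gene's probe sets. The count depended on the 3 mirror fighter arrays: it was 1 without array 1, 0 without array 2 and 9 without array 3. It was 28 without isolated array 1, 22 without isolated array 2, 12 without loser array 1, 28 without loser array 2, 11 without winner array 1, 11 without winner array 2 and 109 without winner array 3. Of the 13 named falls 11 lost their calls in most of the alternative settings, all but ahcy and otpb, and so did the rises of egr4, fech, egr2b and dusp5. With the hybridization control level as a covariate the count was 0, with 1537 at an unadjusted p under 0.05.

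**Figure D4:**
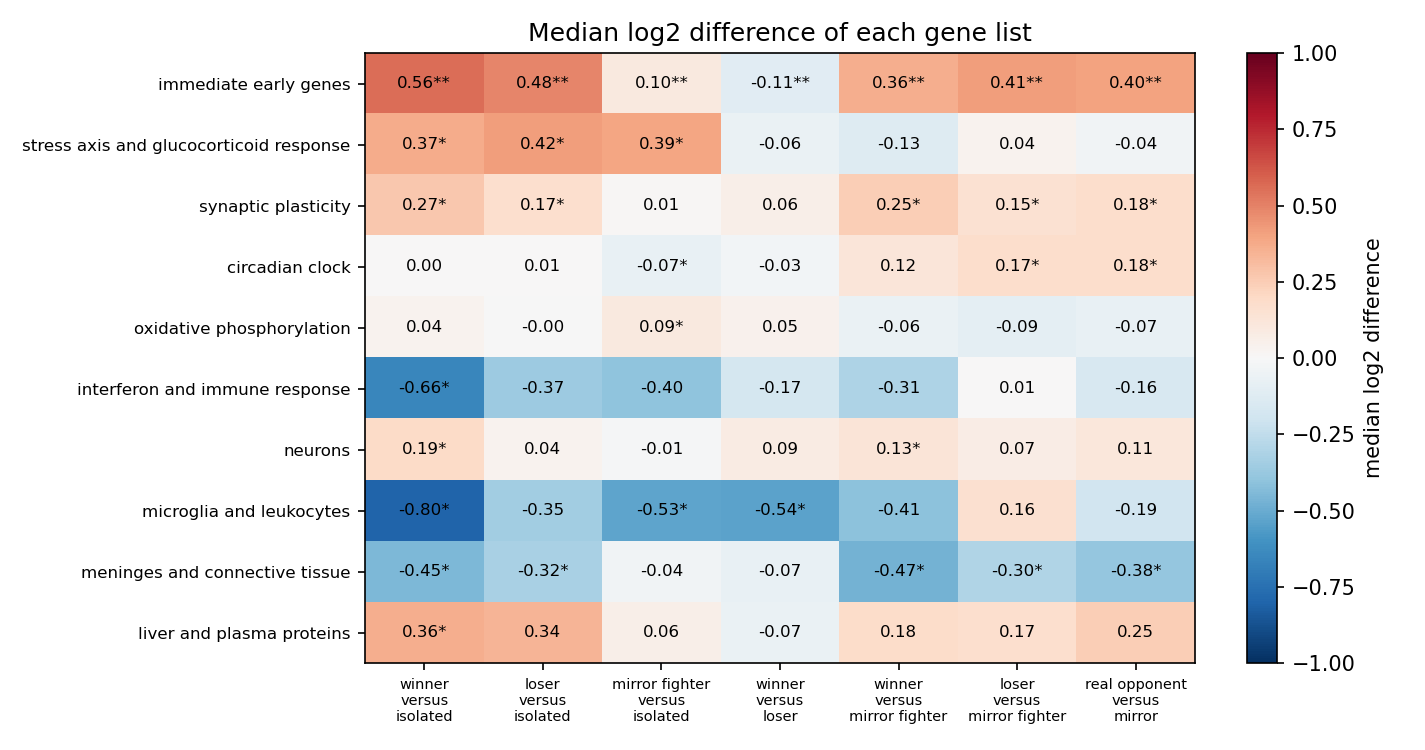
Median log2 difference (colour and number) of the 10 gene lists called in at least 1 of 7 comparisons. One star marks lists called with the preset correlation of camera, and a pair of stars those called also with an estimated correlation, which holds for the immediate early genes in all 7 comparisons.

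The 31 list calls made over the 7 comparisons also depended on the setting, though the 4 settings that follow kept those of the immediate early genes. Quantile normalization kept 22 and ended those of the stress axis in winners and losers and of interferon genes and neurons in winners against isolated fish, of synaptic genes in losers against both, of neurons in winners against mirror fighters, and of clock genes in losers, alone or with winners, against mirror fighters. Averaging a gene's probe sets kept 24 and ended those of interferon genes in winners and of synaptic genes in losers against isolated fish, of meningeal genes in losers against both, and of clock genes in losers against mirror fighters. It also ended the clock and meningeal calls in winners and losers together. With 32 added 30 were kept, all but liver and plasma protein genes. With the hybridization control level as a covariate 15 were kept and 42 others were added, among them skeletal muscle, skin, photoreceptor and proliferation lists, while the synaptic, meningeal, neuronal and clock calls all ended.

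A test for any difference among the 4 groups called 43 probe sets for 30 named genes, and each of the 43 was also called in at least 1 of the pairwise comparisons. At an unadjusted p under 0.05 there were 2889, against 775 by chance. The count was 17 without isolated array 1, 20 without isolated array 2, 24 without loser array 1, 17 without mirror fighter array 1, 26 without mirror fighter array 2, 25 without winner array 1 and 23 without winner array 2.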

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

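The spiked controls were examined after the values were seen, as were the tests of the immediate early genes against the hybridization level and of their 2 smaller steps, and those of microglial markers against the loss of 1 array and against chance movement, and the splits and the bound that respect the pairs of winner and loser arrays, while the other tests of this part were set out before their results were seen.

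The spiked controls, which lie outside the main measurement, read higher in the fish that met a real opponent than in isolated fish. The hybridization controls were higher by a log2 difference of 1.11 in winners and 0.98 in losers, the poly-A controls by 0.44 and 0.42, and the cre control by 0.31 and 0.24.

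The first pattern weighed is that winner and loser arrays differ together from isolated and mirror fighter arrays, in spiked controls as well as in genes such as socs3a, npas4a and otpb. If the hybridization or labelling level of an array drove this, probe sets that follow the controls within groups should follow them between groups. Over all probe sets these quantities correlated at 0.258, and 9 of 100 reshufflings were as high, the highest other at 0.365, so this stays open for the bulk of probe sets. For the probe sets called between winners and losers and mirror fighters, the within-group slopes predicted a median shift of 0.24 (SD over reshufflings 0.16) where 0.96 was observed, but these probe sets were called for a small spread within groups (median residual SD 0.888 of that of probe sets as bright), which keeps such slopes small, so this decides nothing and stays open too. A separate batch of labelling or hybridization for the winner and loser arrays cannot be told apart from having met a real opponent, since all 6 arrays of that kind had the brighter controls, and the biological difference between groups stays open beside it.

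The second pattern is the order of the immediate early genes, lowest in isolated fish, then mirror fighters, winners and losers. Within groups the list mean changed by -0.087 ± 0.043 (SE) per log2 unit of the hybridization controls, so the upper 95% bound of the shift it predicts is 0.0155, against 0.655 observed. This list slope averages slopes of opposite sign. The 14 called members had a slope of 0.215 ± 0.154 and an upper bound of 0.598, against 1.63 observed. These 14 were called on the same arrays, which favours a large observed shift. The other 35 had a slope of -0.208 ± 0.066 and an upper bound of -0.0524, against 0.264 observed. The 35 members not called in winners or losers were still higher in winners and losers than in isolated fish by 0.28 (exact permutation p = 0.0119, the smallest that 84 splits can give, and a lower 95% bound of 0.0991 with each winner and loser pair averaged), so the called members do not carry this rise alone. Of these 35, 25 were above 0 in winners and 26 in losers. They still hold strongly raised members that missed the call, such as cebpd and ier2a. Their mean alone therefore cannot decide whether a few genes carry the rise. The median of all 49 members against isolated fish was 0.56 in winners and 0.48 in losers. Without any 1 array it was at least 0.467 and 0.462. A few genes cannot set a median, so these values argue against a rise carried by a few strongly induced genes. The steps of the 35 uncalled members from isolated fish to mirror fighters (0.0303, SE 0.0293, against 0.192 in all 49) and from winners to losers (0.0218, SE 0.0623, against 0.107) were within their spread, so whether the called members alone carry these steps stays open. The hybridization, poly-A and cre controls differed by 0.02, -0.17 and -0.08 between mirror fighters and isolated fish and by 0.13, 0.01 and 0.07 between winners and losers, so a separate batch stays open at the step between these pairs, where the controls differ most, and was not tested at the smaller steps.

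The third pattern is the lower level of microglial and leukocyte markers in winners than in isolated fish. No 1 array decided the call, since the highest adjusted p over the 12 fits without 1 array was 0.00411. Since 26 of the 27 members were brighter than the cut for dim probe sets, dim probe sets could account for little of it. These 26 had a median of -0.98, 23 of them below 0. The SE of that median over the members, 0.31, takes the markers as independent of each other. With the correlation between these genes estimated from the data the adjusted p was 0.496, so chance movement of genes that vary together between arrays stays open. A biological cause tied to winning was not tested apart from this comparison.

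Other splits of the arrays were counted for each comparison of calls. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 38 and 0 for winners against isolated fish and 88 and 0 for losers against isolated fish, each reached by 1 split, the real one. They were 0 and 0 for mirror fighters against isolated fish, reached by 10 splits, 1 and 1 for winners against mirror fighters, reached by 2, and 27 and 1 for losers against mirror fighters, reached by 1. For winners against losers the real count was 0, reached by all 10 splits, and the highest other was 14, from a split of losers 1 and 2 with winner 1 against loser 3 with winners 2 and 3. That split keeps the numbered pairs 1 and 3 together and points to a structure of these arrays. Among the 4 splits that part all 3 pairs, the real one included, the highest count was 0, and the other 6 part 1 pair. For winners and losers against mirror fighters 1 of 100 drawn splits, the real one, reached 65, the highest other giving 3. Those draws part winner and loser arrays of the same number, and only 10 splits keep these pairs on a side, too few for a share under 0.05, the highest other giving 2. For any difference among the groups 1 of 100 drawn splits reached 43, the highest other giving 2, and so did 1 of 100 that part all 3 pairs as the real one does, the highest other again giving 2, so chance assignment of arrays can be excluded there.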

How the results depend on the processing

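The results with 32 added before log2, with the hybridization control level as a covariate, with winner and loser arrays alone in a replicate block, of single genes with only the arrays compared, and of lists with the block and an estimated correlation were chosen after seeing the data; the other alternatives were planned. Comparisons are named here by their groups, and counts are of called probe sets (genes where a gene's probe sets were averaged). No direction of the 102 gene values called for named genes reversed under any setting, and the immediate early list kept its call in all 7 comparisons under every setting but 2. For winners against losers it did not pass without loser replicate 3 (adjusted p = 0.0813), its median ranging from -0.16 to -0.10 over the arrays left out. With the replicate block and an estimated correlation it did not pass for winners against losers (median -0.11, adjusted p = 0.119) or for mirror fighters against isolated (median 0.10, adjusted p = 0.0864). Where no cause follows from the construction of a setting, the cause was not tested.

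Quantile normalization gave 4 calls for winners against mirror fighters and 37 for real opponent against mirror, and centring on the median 3 and 42. Leaving out the dimmest 25% raised winners against isolated to 59, losers against isolated to 271, winners against mirror fighters to 19, losers against mirror fighters to 71, real opponent against mirror to 316 and any difference to 164. Without moderation the counts were 23 for winners against isolated, 3 for winners against mirror fighters and 145 for real opponent against mirror. With trend and robust moderation they were 162 for losers against isolated, 30 for winners against mirror fighters, 44 for losers against mirror fighters, 215 for real opponent against mirror and 117 for any difference. Averaging a gene's probe sets gave 9 for winners against mirror fighters and 120 for real opponent against mirror. With 32 added, which damps dim values, they were 65 for winners against isolated, 317 for losers against isolated, 31 for winners against mirror fighters, 53 for losers against mirror fighters, 352 for real opponent against mirror and 172 for any difference.

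With the replicate block the counts were 27 for winners against isolated, 75 for losers against isolated, 0 for winners against mirror fighters, 14 for losers against mirror fighters and 27 for real opponent against mirror. Only winner and loser arrays, which the last of these comparisons joins, were paired by number. The same-numbered correlations of other groups ranged from -0.0456 to 0.211 over all probe sets. Over the 7751 brighter ones they ranged from -0.152 to 0.505, the highest for isolated and mirror fighter arrays 3. For winners against losers the block changed no call but that of the interferon list, with 0 probe sets called by limma in the fit of 12 arrays (755 at an unadjusted p under 0.05) and 0 in that of the winner and loser arrays alone (800). With only the arrays compared, and so fewer residual degrees of freedom, the counts were 3 for winners against isolated, 15 for losers against isolated, 1 for winners against losers, 0 for winners and for losers against mirror fighters and 13 for real opponent against mirror.

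The hybridization control level as a covariate ended all calls, 0 for winners and losers against isolated and against mirror fighters, 0 for real opponent against mirror and 0 for any difference. This level parted winner and loser arrays from the others without overlap, so the covariate nearly repeats that division of the arrays. A larger SE follows from this construction, and the lost calls decide nothing about a cause. The SE grew and most of these estimates fell: npas4a in losers against isolated went from 4.14 ± 0.27 to 3.31 ± 0.55, socs3a in real opponent against mirror from 3.12 ± 0.30 to 3.15 ± 0.79, and npas4a there from 2.33 ± 0.24 to 1.47 ± 0.55, while fosab there went from 1.69 ± 0.20 to 0.74 ± 0.42, nr4a1 from 1.68 ± 0.25 to 0.87 ± 0.59 and egr4 from 1.31 ± 0.22 to 0.53 ± 0.52. Smaller changes were those of egr2b in losers against isolated (1.80 ± 0.13 to 1.68 ± 0.28) and junba in real opponent against mirror (1.33 ± 0.15 to 1.37 ± 0.39). The covariate kept 15 of the 31 list calls and added 42. The liver and plasma list in winners against isolated turned to a median of -0.24 under it, and the immediate early list still passed, at an adjusted p of 6.6e-07 in winners and 2.6e-11 in losers against isolated. Over the arrays left out in turn, counts ranged from 15 to 39 for winners against isolated, 21 to 122 for losers against isolated, 0 to 1 for mirror fighters against isolated, 0 to 2 for winners against losers, 0 to 5 for winners against mirror fighters, 0 to 27 for losers against mirror fighters, 0 to 109 for real opponent against mirror and 17 to 48 for any difference. In mirror fighters against isolated, the median of oxidative phosphorylation ranged from -0.027 to 0.19 and that of the circadian clock from -0.18 to 0.0012. Of the 102 gene calls, 79 were kept with quantile normalization, 76 with centring, 73 without moderation, 96 with trend and robust moderation, 64 with the block, 98 with 32 added, 22 with only the arrays compared and 0 with the covariate, and 11 were lost under the covariate alone.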

Other observations

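All gene positions between groups in the first paragraph were worked out after the values were seen, as was the sorting of genes by them.

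The immediate early and synaptic genes that rose in any comparison differed in how far mirror fighters stood on the way from isolated fish to winners and losers. Of 16 such genes, 8 lay over 30% of the way. Among them egr2b stood at 59.1%, nr4a1 at 44.7%, egr4 at 43.7%, npas4a at 41.2% and sik1 at 39.9%, while fosab stood at 36.6% to 58.1% over its 4 probe sets. Another 4 lay between 10% and 30%, namely egr1 (27.3%, and 6.7% by its other probe set), dusp2 (21.8%), dusp5 (14.3%) and junba (12.8%). The remaining 4 lay under 10%: bdnf at 4.69%, gadd45ba at -2.19%, dlg1a at -30.4% and socs3a at -34.9%. Calls against mirror fighters also admitted genes to this set, and dlg1a entered through these alone. Such a selection on the same arrays favours a low position. By another probe set btg2, counted among the 8 at 32.2%, stood at -2.06%, so the sorting depends on the probe set. Whether these sets of genes differ from each other was not tested, and in single genes the values of mirror fighters against isolated fish did not pass over all probe sets.

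Radial glial genes as a list were not called in any comparison, but single members were lower in fish that met a real opponent. Against mirror fighters, her6 and her9 of the 17 members fell over all probe sets in the mean of winners and losers (both adjusted p = 0.0484), calls lost in 16 and 15 of 22 alternative settings. When adjusted over the list alone, slc1a3a (-1.06 ± 0.32, SE, 3 arrays per group), a glial glutamate transporter gene, and her4.2 (-0.88 ± 0.27), named after its value was seen, fell as well. Among 21 neuropeptide genes in the same comparison, none passed over all probe sets and 5 fell adjusted over the list alone, with gnrh3 at -0.72 ± 0.15, adcyap1a at -0.59 ± 0.16 and, named after their values were seen, pmchl at -1.35 ± 0.43, nppc at -0.95 ± 0.32 and nucb2b at -0.68 ± 0.23. In that list 2 rose, the processing enzyme gene cpe (0.43 ± 0.12) and scg2a (0.41 ± 0.14), the latter named after its value was seen. None of 27 interferon and immune genes passed over all probe sets, and 3 did adjusted over the list alone, socs1a at 1.80 ± 0.37, the complement gene cfd at -1.08 ± 0.21 and relb at -0.56 ± 0.11. Of 14 endothelial and mural genes, fli1 (-0.91 ± 0.21) and flt4 (-0.52 ± 0.12) fell adjusted over the list alone, while fli1rs (0.72 ± 0.23) rose.

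Of the 26 lists, 16 were called in none of the 7 comparisons. The smallest adjusted p of each over the comparisons was 0.0598 for eye and pineal photoreceptor genes (median 0.22, losers against mirror fighters), 0.0791 for ribosomal protein genes (-0.04, mirror fighters against isolated fish) and 0.165 for skin and mucosal epithelium (0.24, mirror fighters against isolated fish). In winners against isolated fish it was 0.104 for monoamine genes (0.14), 0.105 for glycolysis and glycogen (0.08), 0.149 for proliferation (-0.14) and for skeletal muscle (0.03), 0.278 for radial glia and astroglia (-0.05), 0.332 for sex steroid signalling (0.12), 0.386 for pituitary genes (0.31) and 0.808 for erythrocyte genes (-0.16). In losers against isolated fish it was 0.411 for endothelium and mural cells (-0.25) and 0.642 for oligodendrocytes and myelin (-0.13). It was 0.661 for neuropeptides (-0.06) in losers against mirror fighters, and in winners against losers 0.665 for ependyma and choroid plexus (-0.07) and 0.808 for heat shock and unfolded protein response (-0.01).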
